A study of Limonium bicolor with 5 samples.

How the data were processed

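Poly(A) RNA was sequenced from first true leaves of Limonium bicolor, a salt-secreting plant, grown in tissue culture. The 5 samples were 5 stages of leaf development, with 1 sample per stage. Per the labels, stage A leaves were undifferentiated, stage B had differentiated salt glands, stage C differentiated stomata, stage D a differentiated epidermis, and stage E leaves were mature. Per the labels, about 5000 leaves were pooled for stage A, 4000 for stage B, 2000 for stage C, and 1000 each for stages D and E. The labels also say that each stage was run in a pair of lanes, called biological replicates there. The table used here gives 1 column per stage, so lanes could not be compared, and no spread between replicates was known.

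The deposited table paired 18327 Limonium gene identifiers with 18327 distinct Arabidopsis loci and their descriptions. Per the file headers, its values are RPKM, a unit that also divides by gene length. The deposited values themselves were RPM (reads scaled to the size of the library, without division by gene length): in each stage, 100% of values were whole multiples of 1 step shared by all genes, within 0.001 reads. Long and short genes of one stage are therefore not comparable in level, whereas the same gene can be compared between stages. The step of each stage gave the number of reads behind it: 5939374 reads behind stage A, 16556653 behind stage B, 14286009 behind stage C, 16367754 behind stage D and 12945184 behind stage E. The aligner, the assembly and the handling of reads that match several genes are not given in the sources used here. Reads of near-identical genes could have been split or moved between loci, so single members of gene families are uncertain. All 5 value columns were mapped to a stage by name.

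A gene was called changed between stages by a fixed rule of size, without a test. The values had to differ by at least 1 on the log2(RPM + 1) scale, the higher stage had to reach 5 RPM, and the largest stage value had to reach 1 RPM, which 18165 genes met. Folds printed for single genes are ratios of RPM without the pseudocount. With 1 sample per stage there was no replicate check and no p-value was computed across genes. The interval beside a fold is the exact 95% interval (Clopper-Pearson) from the recovered reads. Intervals and floors cover counting error only, since amplified reads are not independent molecules. Where a stage had 0 reads, no fold is printed. A count-based call, added after the values had been seen, required the whole interval to lie at 2-fold or more.

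The comparisons (except stage D against stage B), the rule of size, 16 gene lists and the rule for naming genes were fixed before the data were examined. That rule took the 10 called genes with a name that rose most and the 10 that fell most in each comparison. It also took the 5 named genes per stage with the largest ratio of their highest stage to the next (on RPM + 1), and every measured member of the trichome and stomatal lists. For the other lists it took the 2 members that rose most and the 2 that fell most, in comparisons where the list median lay outside the central 95% of random lists. The text names a part of the genes this rule takes. What counts as a name was settled later: 2141 descriptions that say unknown or uncharacterised, give a domain of unknown function, or open with database terms, were passed over. Symbols were paired with Arabidopsis loci by hand from general knowledge, since the table holds none. Members of lists were found by these loci and by words in the descriptions. The words for ion transport also took nucleotide pyrophosphatases, and those for cell division also took histone methyltransferases and an acetyltransferase. Those for the Calvin cycle also took proteins described as Rubisco methyltransferases or as phosphoribulokinase / uridine kinase family. Those for the light reactions also took plastid loci. Those for vessels, phloem and lignin also took genes described as phloem protein 2 and a spermidine hydroxycinnamoyl transferase, so not every member need mark a cell type. The list of cytosolic ribosomal proteins matched 3 genes, and the list of reference genes matched 0.

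A list is described by the median log2 difference of its members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test across samples. Random lists were not matched on chromosome or gene family. Alternatives planned in advance were pseudocounts of 0.1 and 5, no minimum or 20 RPM for the higher stage, a 4-fold rule, and median-of-ratios scaling over 14179 genes. Comparing stage D with stage B, summing over annotation families, thinning reads, splitting them at random into 2 equal parts, leaving out stage C, and lists of ribosomal, repetitive-sequence and clock proteins were added after the values had been seen. A family is the set of genes that share a description once closing numbers are removed.

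The rule and the intervals were tested on simulated reads drawn from the real means and depths of each comparison, with 200 of 18327 genes changed. For stage B against stage A, all 43 genes changed 4-fold and all 58 changed 3-fold were called, and 0 of 49 changed 1.5-fold were. The counting interval held the true 4-fold value in 95.1% of 10501 genes in a simulation of the same comparison. The simulated reads had counting error only. Changed genes and the 10501 were taken only above a minimum level in the first stage. So neither low values nor variation between libraries was tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.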

Results

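Gene expression was measured in 5 stages of the first true leaf of Limonium bicolor, from the undifferentiated leaf to the mature leaf, to follow the differentiation of salt glands. Each stage was 1 library, with 5939374 reads for stage A, 16556653 for stage B, 14286009 for stage C, 16367754 for stage D and 12945184 for stage E. A value of 3 reads, the floor used here, was 0.505 RPM in stage A and between 0.181 and 0.232 RPM in the other stages. Genes are named by the description of the Arabidopsis locus paired with them. No difference below has a replicate check.

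Cell division genes were high in the youngest leaves and photosynthesis genes in later ones. The 57 measured genes of DNA replication and cell division summed to 13198 RPM in stage A, 12957 in stage B, 6577 in stage C, 1173 in stage D and 628 in stage E. The 89 genes of the photosynthetic light reactions summed to 7754 RPM in stage A, 17882 in stage B, 72928 in stage C, 92578 in stage D and 24185 in stage E. Single loci weigh heavily in the stage C sums. Histone H2A 6 (AT5G59870) went from 3788 RPM in stage B to 237 in stage C. Of the 57 cell division genes, 24 fell and 7 rose there (18 and 12 after scaling). Chlorophyll A/B binding protein 3 (AT1G29910) stood at 291 RPM in stage B, 13966 in stage C and 1068 in stage D. Both loci go with the skew of stage C by chromosome given below. The 31 genes of leaf initiation, growth and polarity summed to 1301 RPM in stage A and 324 RPM in stage E. The 34 aquaporins, which carry water and small solutes across membranes, summed to 2171 RPM in stage A and 15943 RPM in stage D.

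**Figure D1:**
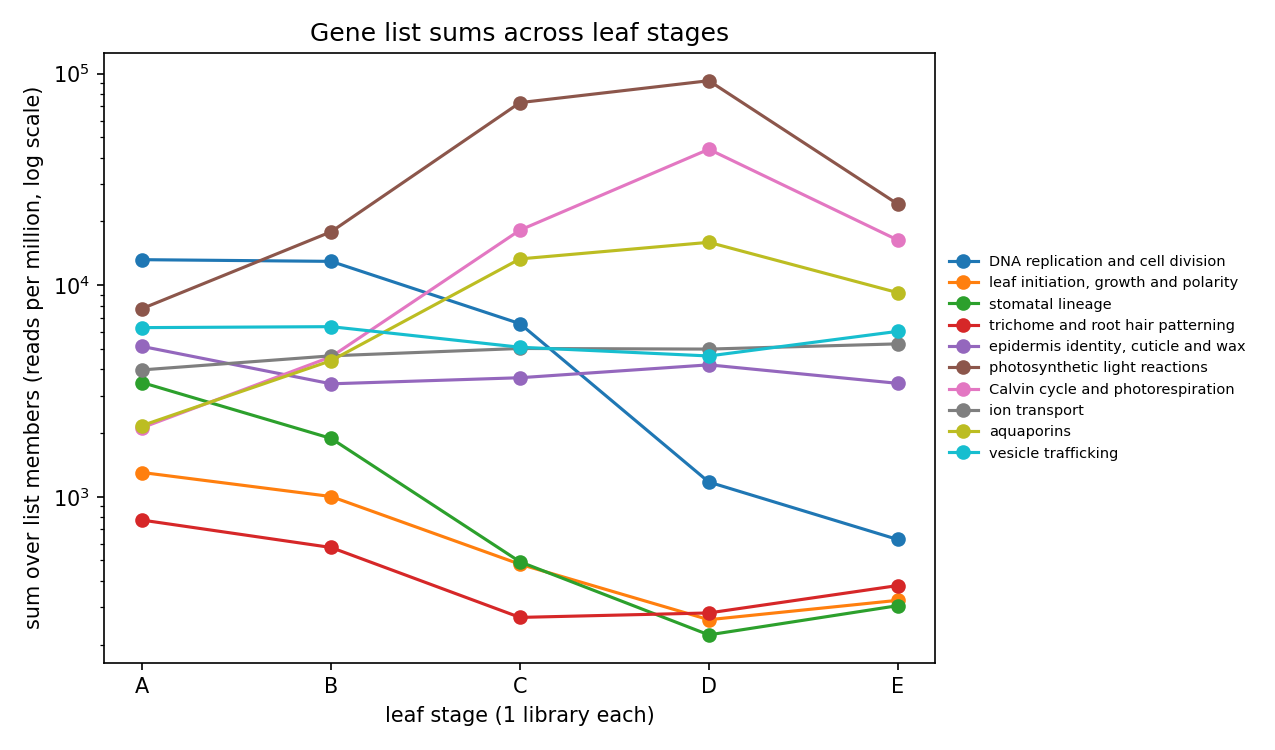
Sums of RPM over the measured members of 10 gene lists (log scale) at each leaf stage, with 1 library per point and no error bars. Cell division genes went from 13198 RPM in stage A to 628 RPM in stage E, and light reaction genes peaked at 92578 RPM in stage D.

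Across 18165 genes, Pearson's correlation of log2(RPM + 1) was 0.956 between stages A and B and 0.918 between stages D and E. Stage C lay apart from both of its neighbours, at 0.785 with stage B and 0.763 with stage D, while stages B and D stood at 0.864. These are correlations across genes, which are not independent replicates. Spearman's values were 0.958, 0.922, 0.790, 0.764 and 0.871 in the same order. Loci matched to Arabidopsis chromosome 1 took 40.4% of the reads of stage C and between 24.4% and 28.3% in the other stages. Loci matched to chromosome 5 took 15.1% in stage C and between 22.0% and 25.0% elsewhere.

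**Figure D2:**
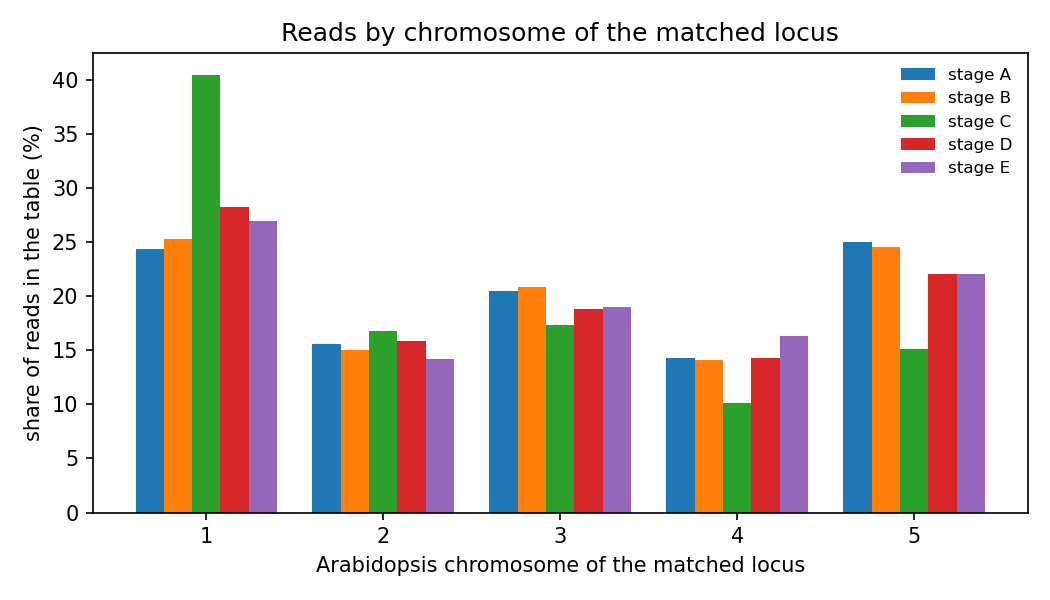
Share of the reads in the table (%) that fell on loci matched to each Arabidopsis chromosome, with 1 bar per stage and 1 library per bar. Stage C had 40.4% on chromosome 1, above all other stages, and 15.1% on chromosome 5, below all other stages.

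The comparison of stage B with stage A asked what differed when salt glands had appeared. Photosynthesis genes rose: 39 of 89 light reaction genes were higher in stage B and 4 were lower, with a median log2 difference of 0.89, above all 10000 random lists. Rubisco activase, which keeps the carbon-fixing enzyme active, rose 3.63-fold (95% counting interval 3.47 to 3.81), from 326 to 1185 RPM. Of 20 Calvin cycle and photorespiration genes 8 rose and 0 fell, and of 34 aquaporins 7 rose (4 after scaling) and 0 fell. Among the genes that rose most were jasmonic acid carboxyl methyltransferase (AT1G19640), which makes methyl jasmonate, at 14.3-fold (9.31 to 23.3), and germin-like protein 1 (AT1G72610) at 12.1-fold (9.09 to 16.5). Beta glucosidase 12 (AT5G42260) rose 10.7-fold (8.61 to 13.4) and beta glucosidase 15 (AT2G44450) 11.3-fold (8.31 to 15.9).

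Of the 15 measured genes of trichome and root hair patterning, 1 was higher in stage B, 3 were lower and 11 did not pass the rule. WER (AT5G14750), a MYB factor of root hair patterning, fell 2.53-fold (2.32 to 2.77), from 161 to 63.4 RPM. MYB23 fell 2.42-fold (2.17 to 2.68) and GL1, a MYB factor needed for trichomes, 2.73-fold (2.22 to 3.36). ETC1, a small MYB repressor in the same network, rose from 12.3 to 28.4 RPM, a call that was lost with median-of-ratios scaling. Of 15 stomatal lineage genes, 3 rose and 1 fell. SPCH (AT5G53210), which starts the stomatal lineage, rose 2.37-fold (1.83 to 3.11) to 26.7 RPM. TMM, a receptor that spaces stomata, rose 5.19-fold (3.18 to 9.06), and SDD1, a protease of the same process, 6.56-fold (3.09 to 16.6). ERECTA fell 2.05-fold (2.01 to 2.10), from 2415 to 1176 RPM. The median of the stomatal list was 0.46 and turned to -0.49 over members that reached 5 RPM.

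Cuticle and wax genes had a median log2 difference of -0.43, below all random lists; 6 of 38 fell and 0 rose. CER1, an enzyme of wax alkane synthesis, fell 2.66-fold (2.52 to 2.81) and CER4 3.61-fold (2.62 to 4.99). Of 31 leaf initiation and growth genes 3 fell and 1 rose. The homeobox genes STM and KNAT1, which mark the shoot meristem, both stood at 7.41 RPM in stage A and fell 13.6-fold (6.57 to 31.8) and 8.76-fold (4.71 to 17.3). The genes that fell most included an F-box protein (AT1G47300), 34.4-fold (32.6 to 36.2), and a HhH-GPD DNA repair protein (AT4G12740), 50.6-fold (48.1 to 53.3). They belonged to 12 loci that stood over 10 times higher in stage A than in any other stage (on RPM + 1) and held 3.19% of its reads. In all, 1920 genes changed, 1357 higher and 563 lower; 1081 also passed the count-based call. Median-of-ratios scaling gave 950 higher and 813 lower, so the balance of directions depended on the scaling.

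The comparison of stage C with stage B concerned the appearance of stomata. Photosynthesis genes were higher again: 42 of 89 light reaction genes rose and 7 fell (53 and 3 after scaling), with a median log2 difference of 0.96, above all random lists. Of 20 Calvin cycle and photorespiration genes 12 rose and 1 fell, and 18 of 34 aquaporins rose and 3 fell. The Calvin cycle list member that fell was AT1G73980, described as phosphoribulokinase / uridine kinase family. Of 62 ion transport genes 8 rose and 9 fell, a balance that scaling turned to 13 and 7; their median was 0.17, at percentile 99.9 of random lists. Of 46 vessel, phloem and lignin genes, a list meant for other cell types, 9 rose (14 after scaling) and 2 fell, with a median at percentile 99.1. In leaf initiation and growth, 17 of 31 genes fell and 1 rose. ANT, a promoter of organ growth, fell 19.8-fold (16.5 to 23.9) and growth-regulating factor 5 fell 9.29-fold (7.60 to 11.5). In the trichome list 9 of 15 genes fell (6 after scaling) and 0 rose, with a median at percentile 3.84, inside the central 95% of random lists. None of the 9 was a locus of chromosome 1, which took a larger share of the reads in stage C. GL3 fell 5.32-fold (4.29 to 6.66) and CPC 5.15-fold (4.31 to 6.18). Of the stomatal genes 6 fell and 1 rose, against 4 and 2 after scaling, with a median at percentile 51.4. SPCH fell 4.89-fold (3.84 to 6.30), while TMM stood at 14.9 RPM in stage B and 14.8 RPM in stage C.

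In total 2786 genes were higher in stage C and 4178 lower. The median of all genes was -0.24 on the log2 scale; relative to it, light reaction genes stood at 1.21 and leaf growth genes at -0.94. Scaling gave 3668 higher and 2864 lower, the opposite balance. Loci of chromosome 1 made up 46.1% of the higher genes and 14.3% of the lower ones. Loci of chromosome 5 made up 10.6% of the higher and 34.8% of the lower ones. List counts and folds in comparisons with stage C may carry this skew. The largest rises included xyloglucan endotransglucosylase/hydrolase 17 (AT1G65310), at 0.181 RPM in stage B, 268 in stage C and 2.20 in stage D. RAB GTPase homolog A3 (AT1G01200) rose to 179 RPM in stage C and had 0 reads in stages B and D.

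The comparison of stage D with stage C concerned the differentiation of the epidermis. Of 38 epidermis, cuticle and wax genes 10 rose and 11 fell (11 and 10 after scaling), with a median at percentile 35.5 of random lists. Cell division genes fell in 46 of 57 cases and rose in 0, with a median log2 difference of -2.29, below all random lists. Histone H2A 2 (AT4G27230) fell 38.0-fold (32.1 to 45.2). Light reaction genes rose in 36 of 89 cases and fell in 12. Of 46 vessel, phloem and lignin genes 14 rose and 3 fell, with a median of 0.57 at percentile 99.9. In the stomatal list 7 of 15 genes fell and 1 rose: TMM fell 7.84-fold (5.36 to 11.8), SCRM2 3.87-fold (3.26 to 4.61) and SPCH 5.96-fold (3.40 to 11.2), and YDA rose 3.13-fold (2.67 to 3.68). In the trichome list 4 genes rose, among them MYB23 by 5.34-fold (4.38 to 6.57), and 2 fell. Those that rose were loci of chromosomes 4 and 5 and those that fell were loci of chromosome 1. A change with stage cannot be told apart here from the skew of stage C by chromosome. Of 94 heat shock genes, 20 fell and 11 rose; an HSP70 gene (AT1G09080) stood at 5.92 RPM in stage B, 1526 in stage C and 3.91 in stage D. In all, 3166 genes were higher and 3546 lower, against 3479 and 3446 after scaling. Loci of chromosome 1 made up 42.7% of the lower ones and 14.4% of the higher ones.

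Stage D was also compared directly with stage B, a comparison added because stage C lay apart. Cell division genes fell in 45 of 57 cases and rose in 3, all of them histone methyltransferases taken by the words of the list. Cyclin B2;2 fell 38.4-fold (29.9 to 50.1). Light reaction genes rose in 72 of 89 cases and fell in 1. Carbonic anhydrase 1 (AT3G01500), which interconverts carbon dioxide and bicarbonate, rose from 44.3 to 4009 RPM. Of 31 leaf growth genes 17 fell and 0 rose. Of 38 cuticle genes 7 rose and 5 fell (10 and 3 after scaling), with a median of 0.35, above all random lists. Aquaporins rose in 14 of 34 cases and fell in 0. In the trichome list 9 of 15 genes fell and 1 rose, against 4 and 1 after scaling, with a median at percentile 0.51. GL3 fell 2.64-fold (2.26 to 3.09), GL2 3.82-fold (2.84 to 5.20), and MYB23 stood at 46.6 and 42.6 RPM. In the stomatal list 6 of 15 fell and 0 rose, including SPCH by 29.1-fold (17.5 to 52.5). Of 46 genes of vessels, phloem and lignin, 21 rose and 2 fell. Of 15 senescence genes 4 rose (6 after scaling) and 2 fell, with a median at percentile 98.2. The median of all genes was -0.29; 1911 genes were higher and 3537 lower, against 2850 and 2012 after scaling.

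The comparison of stage E with stage D set the mature leaf against the leaf with a differentiated epidermis. Light reaction genes fell in 55 of 89 cases and rose in 4, with a median of -1.39, or -1.67 relative to the median of all genes, which was 0.28. Light-harvesting genes 2.1 and 2.2 of photosystem II (AT2G05100, AT2G05070) fell 46.1-fold (43.3 to 49.1) and 42.9-fold (40.6 to 45.5). The 4 that rose were all plastid loci, in libraries made from poly(A) RNA. Among these, the gene for reaction center protein A of photosystem II rose 8.15-fold (7.73 to 8.60). Genes that rose most included dormancy-associated protein-like 1 (AT1G28330), 67.9-fold (61.2 to 75.6), and a dehydrin (AT1G54410), a family linked to water loss, 29.7-fold (27.6 to 31.9). Also among these were ZRT/IRT-like protein 2 (AT5G59520) 68.5-fold (54.1 to 88.0), zinc transporter 11 (AT1G55910) 36.6-fold (30.4 to 44.5) and ferric reduction oxidase 5 (AT5G23990) 68.0-fold (41.6 to 119).

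A GDSL lipase (AT5G33370) fell 85.3-fold (70.4 to 104) and Li-tolerant lipase 1 (AT3G04290) 73.2-fold (58.6 to 92.5). The locus of LHY (AT1G01060), a morning clock gene, fell 126-fold (75.2 to 232). Cell division genes fell in 15 of 57 cases and rose in 1. Of 20 Calvin cycle genes 7 fell and 3 rose, against 10 and 2 after scaling. Those that rose were taken by the words of the list. AT1G26190 and AT1G73980 are described as phosphoribulokinase / uridine kinase family, and AT5G14260 as a Rubisco methyltransferase family protein. Of 15 stomatal genes 1 fell and 0 rose. Their median of -0.24, at percentile 1.17 of random lists, turned to 0.066 over members that reached 5 RPM. Of 46 vessel, phloem and lignin genes 15 fell and 6 rose, against 22 and 2 after scaling. Laccase 17 fell 7.44-fold (6.13 to 9.10) and the phloem sucrose carrier SUC2 rose 2.88-fold (2.65 to 3.13). All others that rose are described as members of the phloem protein 2-A group. Of 34 aquaporins 6 fell and 0 rose, against 15 that fell after scaling. In all, 2376 genes were higher and 1208 lower; scaling turned this to 1113 higher and 1864 lower.

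**Figure D3:**
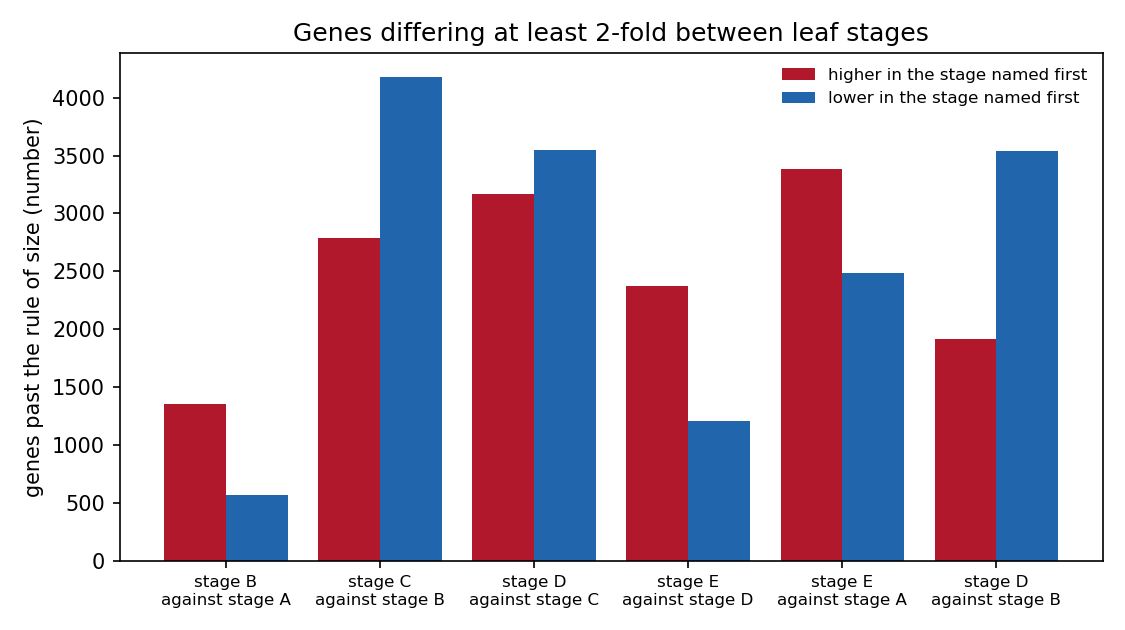
Number of genes past the 2-fold rule of size in each comparison of leaf stages (1 library each), with red bars for higher and blue bars for lower values in the stage named first. Over single genes, comparisons with stage C have the most calls, at 6964 against stage B and 6712 in stage D against stage C. Over sums of annotation families D against B had the most changes, at 1946, against 1687 for C against B. With median-of-ratios scaling the balance turned in 4 of the 6 comparisons (C against B, D against C, E against D and D against B).

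The comparison of stage E with stage A spanned the whole series. Cell division genes fell in 46 of 57 cases and rose in 1. MCM4 and MCM5, parts of the helicase that opens DNA for replication, fell 341-fold (242 to 496) and 273-fold (212 to 360). Topoisomerase II (AT3G23890) fell 263-fold (210 to 333). Of 31 leaf initiation and growth genes 21 fell and 1 rose. Genes of the MtN3 family, to which sugar exporters belong, were among those that rose most, with AT3G48740 at 184-fold (130 to 269) and AT5G23660 at 149-fold (109 to 207). Of 62 ion transport genes 14 rose and 2 fell, with a median at percentile 97.9. Vessel, phloem and lignin genes also rose, in 14 of 46 cases with 4 falling (percentile 99.6), and 28 of 94 heat shock genes fell and 9 rose (percentile 1.05). HKT1 (AT4G10310), a sodium transporter, rose 50.3-fold (32.1 to 83.6), from 3.20 to 161 RPM, and chloride channel A rose 7.08-fold (5.09 to 10.1). Both genes that fell in that list were nucleotide pyrophosphatases, which do not move ions. Of 20 Calvin cycle genes 14 rose and 0 fell, of 34 aquaporins 14 rose and 1 fell, and of 89 light reaction genes 52 rose and 2 fell (50 and 4 after scaling).

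In the trichome list 3 genes fell and 1 rose: GL1 fell 25.3-fold (15.2 to 45.3), WER from 161 to 7.11 RPM and MYB23 15.5-fold (12.5 to 19.5), and a CAPRICE-like MYB (AT4G01060) rose 5.46-fold (3.78 to 8.16). TTG1, EGL3, GL3, TRY, CPC, TTG2, MYB5, TT8, GL2, ETC1 and SAD2 did not pass the rule. The median of the trichome list lay at percentile 1.95 of random lists. In the stomatal list 6 of 15 genes fell, with ERECTA at 20.4-fold (19.3 to 21.5), and 0 rose. FAMA, which completes guard cells, fell 4.00-fold (2.84 to 5.68). MUTE, EPF1, EPF2 and EPFL9 stayed under 5 RPM in every stage, where the rule calls no change. ICE1 was highest in stage B at 19.6 RPM, and FLP in stage C at 19.7 RPM. Of 38 cuticle genes 9 fell and 3 rose (11 and 2 after scaling), and GPAT8 fell 16.8-fold (14.3 to 19.8). Senescence genes rose in 8 of 15 cases and fell in 2, with a median at percentile 99.7. In all, 3385 genes were higher and 2481 lower.

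Of 108 vesicle trafficking genes 13 rose and 3 fell between stages A and E (11 and 6 after scaling), with a median at percentile 59.4; between stages A and B 5 rose and 1 fell (3 and 1 after scaling), with a median of -0.03 at percentile 1.95. Of 6 guard cell genes, 2 rose and 1 fell between stages A and E, with a median at percentile 89.1. The 3 matched genes of cytosolic ribosomal proteins all fell between stages A and E.

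Among 15603 genes that reached 5 RPM, 3361 had their highest value in stage A, 2737 in stage B, 3718 in stage C, 1753 in stage D and 4034 in stage E. Median-of-ratios scaling gave 3763, 1516, 4504, 2814 and 3029 in the same order, so the stage with the most depended on the scaling. The highest stage was at least 2 times every other in 234 genes for stage A, 81 for stage B, 1610 for stage C, 344 for stage D and 800 for stage E, against 338, 33, 1919, 532 and 503 after scaling. Stage D was led by beta-amylase 3 (AT5G18670) at 487 RPM and 8.43 times the next stage on the RPM + 1 scale. Stage E was led by a nucleotide hydrolase-like protein (AT3G62550), at 557 RPM and 61.0 times the next stage. Stage B was led by a thaumatin family protein (AT1G75800) at 3.33 times the next stage.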

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

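Family sums, thinned reads, the count-based call, peaks without stage C and genes alone in their family were chosen after the data had been seen. No paired analysis was possible because each stage has 1 column, and for the same reason the lane pairs, the limma fit on lanes and its replicate block were not run. Depth limits the lowest values: 3 reads are 0.505 RPM in stage A. The cause of the changes below was not tested, except where a stricter rule keeps fewer genes or families are fewer than genes. A 4-fold rule left 203 genes for B against A, 2659 for C against B, 2810 for D against C, 711 for E against D and 2193 for E against A. Sums over 5890 families gave 619, 1687, 1649, 1063 and 1889 changed families in the same order, and 1946 for D against B. A pseudocount of 5 gave 1128 genes for B against A and 2389 for E against D. A minimum of 20 RPM gave 1169 for B against A and 4319 for D against C. The count-based call gave 1081 for B against A. Scaling put 1516 highest values in stage B, 4504 in stage C, 2814 in stage D and 3029 in stage E, and a minimum of 20 RPM put 2403 in stage C.

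Of the list medians, 1 reversed: stomatal genes in E against D went from -0.24 to 0.066 with a minimum of 5 RPM. Scaling moved medians in E against D to -0.24 for cuticle genes, -0.58 for cytosolic ribosomal proteins, -0.029 for ion transport, -0.99 for aquaporins, 0.015 for vesicle trafficking and 0.033 for heat shock genes. In C against B it gave 1.31 for light reactions, 1.99 for cytosolic ribosomal proteins and 0.51 for ion transport. In B against A it gave 0.51 for cytosolic ribosomal proteins, -0.0057 for ion transport, -0.17 for vesicle trafficking and -0.10 for heat shock genes. The other 211 values of list medians stayed within the interval of their median (for the list of 3 genes, within the range of its members). Signs also changed for medians inside the random range: stomatal genes in B against A with a minimum of 5 RPM (0.46 to -0.49), and with scaling 13 others, of the stomatal, cuticle, cell division, ion transport, leaf growth, senescence and heat shock lists.

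Of 50 alternative correlations 39 moved beyond their 95% interval, with stage C lowest among neighbours over single genes. With a minimum of 5 RPM they were 0.943 for A and B, 0.656 for A and C, 0.734 for A and D, 0.743 for A and E, 0.719 for B and C, 0.816 for B and D, 0.774 for B and E, 0.691 for C and D, 0.592 for C and E, and 0.891 for D and E. A pseudocount of 0.1 gave 0.948 for A and B, 0.698 for A and C, 0.804 for A and E, 0.740 for B and C, 0.870 for B and D, 0.830 for B and E, 0.713 for C and D, and 0.637 for C and E. Family sums gave 0.966 for A and B, 0.848 for A and C, 0.843 for A and D, 0.861 for A and E, 0.895 for B and C, 0.894 for B and D, 0.885 for B and E, 0.885 for C and D, 0.840 for C and E, and 0.946 for D and E. Genes alone in their family gave 0.953 for A and B, 0.780 for A and C, 0.794 for A and D, 0.818 for A and E, 0.840 for B and C, 0.853 for B and E, 0.827 for C and D, 0.775 for C and E, and 0.935 for D and E. Thinning gave 0.954 for A and B and 0.914 for D and E.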

Other observations

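The tests of neighbouring pairs over all families, of family sums, of repetitive proteins and of the stage A loci were written after their results, or values closely tied to them, had been seen. The tests of later family members, of read depth at stage C and of further clock genes were written before. That a bound inside a counting interval or a sign that depends on the set of genes or families decides nothing, and that the database hits of the stage A loci could not decide, was settled after these values had been seen; by the rules used first, the pairs and the family sums (by the lower correlation alone) counted for, and the later pairs and the database hits against, their explanations.

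The 326 nuclear genes described as ribosomal proteins, a list added after the values had been seen, summed to 49402 RPM in stage A, 67273 in stage B, 57056 in stage C, 25009 in stage D and 24770 in stage E. In stage B 65 rose and 9 fell against stage A (46 and 11 after scaling), and between stages B and D 233 fell and 7 rose, against 201 and 18 after scaling. Transcripts of 87 plastid loci summed to 2502 RPM in stage A, 2069 in stage B, 1941 in stage C, 7785 in stage D and 13442 in stage E, in libraries made from poly(A) RNA.

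Stage C stood apart from stages B and D also after every library was thinned to the depth of stage A, with a lower correlation of 0.760, which argues against read depth. This could be foreseen, because stage C had 14286009 reads, not far from 16556653 in stage B and 16367754 in stage D. In 77.2% of 2233 annotation families the first listed locus held a larger share at stage C than on average elsewhere. In the other stages, whose average elsewhere includes stage C, it was 28.2 to 31.0%. Families are listed in locus order, so a first locus often lies on an earlier chromosome than the rest. The skew by chromosome could alone give this excess, so it cannot show whether reads of similar genes were given to earlier loci. Neighbouring pairs lie on the same chromosome. Among them the first locus held a larger share in 64.2% of 444 (exact 95% interval 59.5 to 68.7), against 38.1 to 42.6% in the other stages. Without first listed members it was 59.1% of 325 (53.5 to 64.5), against 42.5 to 44.9%. Earlier loci thus held larger shares on average at stage C than at any other stage. The bound of 60%, set in advance only for the last test, lies inside both intervals, so whether reads were moved stays open. Moves of reads within annotation families would not explain that genes alone in their family also ran from a median log2 difference (stage C against the mean of B and D) of 0.13 on chromosome 1 to -0.40 on chromosome 5, against 0.38 to -0.54 for genes with others in their family; similar genes with other descriptions were not tested. A state of its own at stage C also stays open: over all family sums the correlation was 0.885 for C and D and 0.895 for B and C, against 0.894 for B and D, and the gap from the lower one to that of B and D was -0.04 over genes alone in their family but 0.03 over sums of families of 2 to 30 members. Proteins of repetitive sequence, chosen partly after single loci had been seen and tested without those, had a median log2 difference of -0.53 in stage C against the mean of B and D, below all random lists. This was the result predicted if repetitive sequence had been handled differently there. That prediction was written after this result, or values closely tied to it, had been seen. Random lists were not matched on chromosome or family, so this result cannot be told apart from the skews by chromosome and listing order.

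The 12 loci over 10 times higher in stage A summed to 31945 RPM there and 1412 in stage B, and all 12 were lowest in stage C. Counting error at low depth was examined by 200 random splits of the reads of every stage into 2 equal parts. Of the loci chosen by the same rule in 1 part, a median of 100% stood over 10 times higher in stage A in the other. The lowest was 76.9%, and the median ratio to the next stage in the other part was 16.7. This argues against counting error only, and could be foreseen from the median of 18352 stage A reads per locus. Splits of 1 library cannot show reads copied from the same molecule. The splits replaced, after those counts were known, a test on read counts that could not decide. The median of 1.74 database hits per protein, in the 5 members with a count, says nothing on repetitive sequence, because its value comes from a count that 157 genes outside the 12 loci carry as well. A biological difference of the undifferentiated leaf was not tested.

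Clock genes moved in opposite directions between stages D and E. LHY and CCA1 went from 137 to 1.08 and from 28.7 to 0.463 RPM, and TOC1 from 0.244 to 29.2 RPM. Among clock loci not looked at before, the median log2 difference of 6 morning loci lay at -2.77 relative to that of 3 evening loci, which is consistent with leaves of the stages having been collected at different times of day. The morning loci did not move as one, from -3.87 to 1.43 with PRR7 higher in stage E, and a change of the clock with leaf age was not tested. Light-harvesting genes, which also follow the time of day in plants, fell in the same comparison. Clock genes also differed among the earlier stages. From stage A to stage D, LHY stood at 21.9, 27.3, 77.1 and 137 RPM and TOC1 at 11.3, 8.64, 2.10 and 0.244 RPM. CCA1 stood at 7.24, 5.62, 3.43 and 28.7 RPM. Whether time of day enters the other comparisons, including the rise of light reaction genes to stage D, was not tested.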
